A study of Mus musculus with 31 samples.

How the data were processed

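Bulk RNA-seq of macrophages grown from mouse bone marrow (C57BL/6J, male, 6 to 12 weeks old) was used, with 21 libraries in experiment 1 and 10 in experiment 2. The values are raw counts per Ensembl gene, deposited by the authors with 1 column per library, and all columns were used. Per the labels the genome build is mm10, and fastp, STAR and DESeq2 are named without roles or versions. Which step counted reads per gene, the annotation release and the strand setting are not given in the sources used here. The tables hold 35275 and 54532 gene identifiers, of which 34490 (97.77%) and 54409 (99.77%) have a symbol in the reference used here. Of these identifiers, 14981 and 28733 have no count in any library. Symbols, positions, transcript lengths and GC contents came from GENCODE M21 (mm10). Transcript length here means the summed length of all exons of a gene over its transcripts, with overlaps counted once. GC content is that of the longest transcript. Gbp5, Gbp6 and Gbp10 are not analysed here in experiment 1, nor Hbb-b1 in either experiment, because no identifier in the tables was matched to them.

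Groups were taken from the labels, and each experiment was fitted alone, with 1 coefficient per group. Genes were kept by filterByExpr by group (minimum count 10, minimum total 15), which left 12662 and 13313 genes. Counts were scaled by library totals and TMM factors, and tested by quasi-likelihood F tests in edgeR 4.0.16 (R 4.3.3). A gene is called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in the comparison. Every adjusted p of a gene is from edgeR unless another tool is named. The SE of a log2 fold change is its size divided by the square root of F. CPM are counts per M (mega) of TMM-scaled library totals. Between replicates the common biological coefficient of variation was 6.79% in experiment 1 (14 residual degrees of freedom) and 10.6% in experiment 2 (5 residual degrees of freedom). The chi-square between 2 libraries compares their counts over genes with at least 20 counts in the pair with those expected from the totals, where 1 per degree of freedom is counting error alone. Depth was 19.3 to 29.9 M counts in experiment 1 and 14.5 to 17.9 M in experiment 2. TMM factors were 1.275 to 1.286 in the vehicle libraries of experiment 1 and 1.373 to 1.453 in those of experiment 2. In tests on simulated data made with planted changes in 100 genes per fold, iBRD9 + LPS against LPS recovered 72% of 1.5-fold and 85% of 2-fold changes, and the interaction of Dex and iBRD9 48% and 82%. For dBRD9 + IFNγ + LPS against IFNγ + LPS these shares were 32% and 60%, and for the interaction in experiment 2 they were 4% and 36%.

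The 15 comparisons, their tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from the 3 alternatives named last below. An interaction is the compound's log2 fold change with Dex minus that without Dex. Named genes are 16 fixed genes, and per comparison up to 6 with the highest and up to 6 with the lowest log2 fold change among called genes. These have a mean of at least 10 CPM in the higher group and no overlap between the libraries of both groups. Chance alone gives no overlap for 10% of genes with 3 against 3 libraries, and for a larger share with the 2 against 2 of experiment 2. Interactions need 10 CPM in the highest of 4 groups and have no overlap condition. Names that are only clone or locus numbers and pseudogenes were left out. Not every gene that the rule allows is reported. Genes said to have the largest rise or fall, or the highest or lowest value, are ranked only among genes that meet these conditions. In each list up to 4 called members with the largest absolute log2 fold change and at least 10 CPM are eligible, or, where fewer than 2 are called, the 2 members with the highest CPM. A fold against a group without reads is a lower bound with 3 counts over the group as the floor. With 1 to 3 reads the ratio has an exact 95% interval. These floors and intervals cover counting error only. The 95% intervals of differences between the compounds use the SE and a t distribution.

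The 29 gene lists, written by hand, were inflammatory cytokines and chemokines, NF-κB subunits, inhibitors and targets, immediate early transcription factors, type I interferon-induced genes, interferon-inducible GTPases, antigen presentation, genes induced by the glucocorticoid receptor, markers of alternative activation, macrophage identity, BAF subunits, cholesterol synthesis, liver X receptor (LXR) targets, cell cycle and DNA replication, glycolysis and HIF1 targets, NRF2 targets, the unfolded protein and integrated stress responses, heat shock, p53 targets, lysosome, oxidative phosphorylation, mitochondrial transcripts, replication histones, and markers of neutrophils, B cells, T and NK cells, dendritic cells, stromal cells, mast cells and basophils, and erythroid cells. Lists with at least 5 tested members were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and adjusted over the lists of a comparison. An adjusted p given "with an estimated correlation" is from camera with the correlation between genes estimated from the data. Counts "adjusted over the list alone" use a Benjamini-Hochberg correction over the members only.

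Fold changes were set side by side across genes. For the compounds, which share their controls, 100 draws with shared controls and no effect of either compound gave the correlation that shared controls make in unchanged groups. This is not their part of r in data with real changes, so the covariance is given too. The alternatives were DESeq2 size factors in edgeR, library totals without TMM factors, no filter (at least 1 count), a stricter filter (at least 1 CPM in as many libraries as the smallest group holds), DESeq2 1.42.0 Wald tests, limma voom, a fit of the compared groups only, the replicate number as a block, and leaving out each library in turn. For lists they were the estimated correlation and fry. After the data were seen, 3 were added: leaving out the first Dex + LPS and the first Dex + dBRD9 + LPS library together, and taking out each library's trend with transcript length or with GC content as an offset. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.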

Results

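Macrophages were grown from the bone marrow of male C57BL/6J mice in medium conditioned by L-929 cells, and their RNA was sequenced in 2 experiments with 31 libraries in all. The compounds were dexamethasone (Dex, 1 µM), a synthetic glucocorticoid, iBRD9 (3 or 10 µM), an inhibitor of the bromodomain of BRD9, and dBRD9 (250 nM), a compound that degrades BRD9. BRD9 is a subunit of the non-canonical BAF chromatin remodelling complex. The labels do not say which sample had which dose of iBRD9, so the 2 compounds cannot be set side by side at matched doses. Compounds were given overnight and LPS, a bacterial cell wall component, at 100 ng/ml for the last 3 h. Experiment 1 had 3 libraries in each of 7 groups: vehicle, LPS, Dex + LPS, iBRD9 + LPS, dBRD9 + LPS, Dex + iBRD9 + LPS and Dex + dBRD9 + LPS. Experiment 2 had 2 libraries in each of 5 groups, with interferon-gamma (IFNγ, dose and timing not given in the sources used here) named beside LPS: vehicle, IFNγ + LPS, Dex + IFNγ + LPS, dBRD9 + IFNγ + LPS and Dex + dBRD9 + IFNγ + LPS.

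The total count per library (in M, mega) in experiment 1 was 21.6, 26.8 and 20.8 M for vehicle, 24.6, 29.7 and 20.5 M for LPS, and 24.0, 19.3 and 23.1 M for Dex + LPS. It was 29.9, 24.7 and 23.7 M for iBRD9 + LPS, and 22.1, 23.5 and 22.5 M for dBRD9 + LPS. Dex + iBRD9 + LPS had 20.1, 19.4 and 21.0 M, and Dex + dBRD9 + LPS had 25.8, 24.9 and 21.0 M. In experiment 2 it was 14.5 and 16.1 M for vehicle, 17.9 and 15.4 M for IFNγ + LPS, and 15.4 and 15.5 M for Dex + IFNγ + LPS. The dBRD9 + IFNγ + LPS libraries had 15.5 and 15.5 M, and Dex + dBRD9 + IFNγ + LPS had 15.5 and 15.9 M. The test covered 12662 genes in experiment 1 and 13313 in experiment 2. In the first Dex + LPS library and the first Dex + dBRD9 + LPS library, the deviation from the mean of the group fell with transcript length, with Spearman rho across 7426 genes of -0.683 and -0.52 (genes are not independent replicates). The other libraries of these groups had positive values, which follows in part from the measure, since deviations within a group balance out. These 2 libraries stood apart by length in that their rho was the lowest in experiment 1. Smaller trends were present elsewhere, with -0.334, 0.433 and -0.0736 in the dBRD9 + LPS libraries. Chi-square per degree of freedom between libraries of a group was 42 and 44.8 for the Dex + LPS library, 12.4 and 12.8 for the Dex + dBRD9 + LPS library, 11.4 and 11.4 for the third vehicle library, and 2.13 to 5.98 for the other pairs of experiment 1. That vehicle library had 0.658% of counts in genes that collect ribosomal RNA reads, against 0.0781% and 0.0912% in the other vehicle libraries. In experiment 2 the chi-square was 3.18 to 30.9, and the share was 0.202% in the first IFNγ + LPS library and 1.45% to 3.24% in the others. In experiment 2, where the libraries of a pair mirror each other, rho was -0.634 and 0.634 for vehicle and 0.577 and -0.577 for Dex + IFNγ + LPS, and which of a pair stands apart cannot be told. The labels do not say whether replicates were separate animals or cultures, so each p measures only the spread between these libraries, part of which may be technical.

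**Figure D1:**
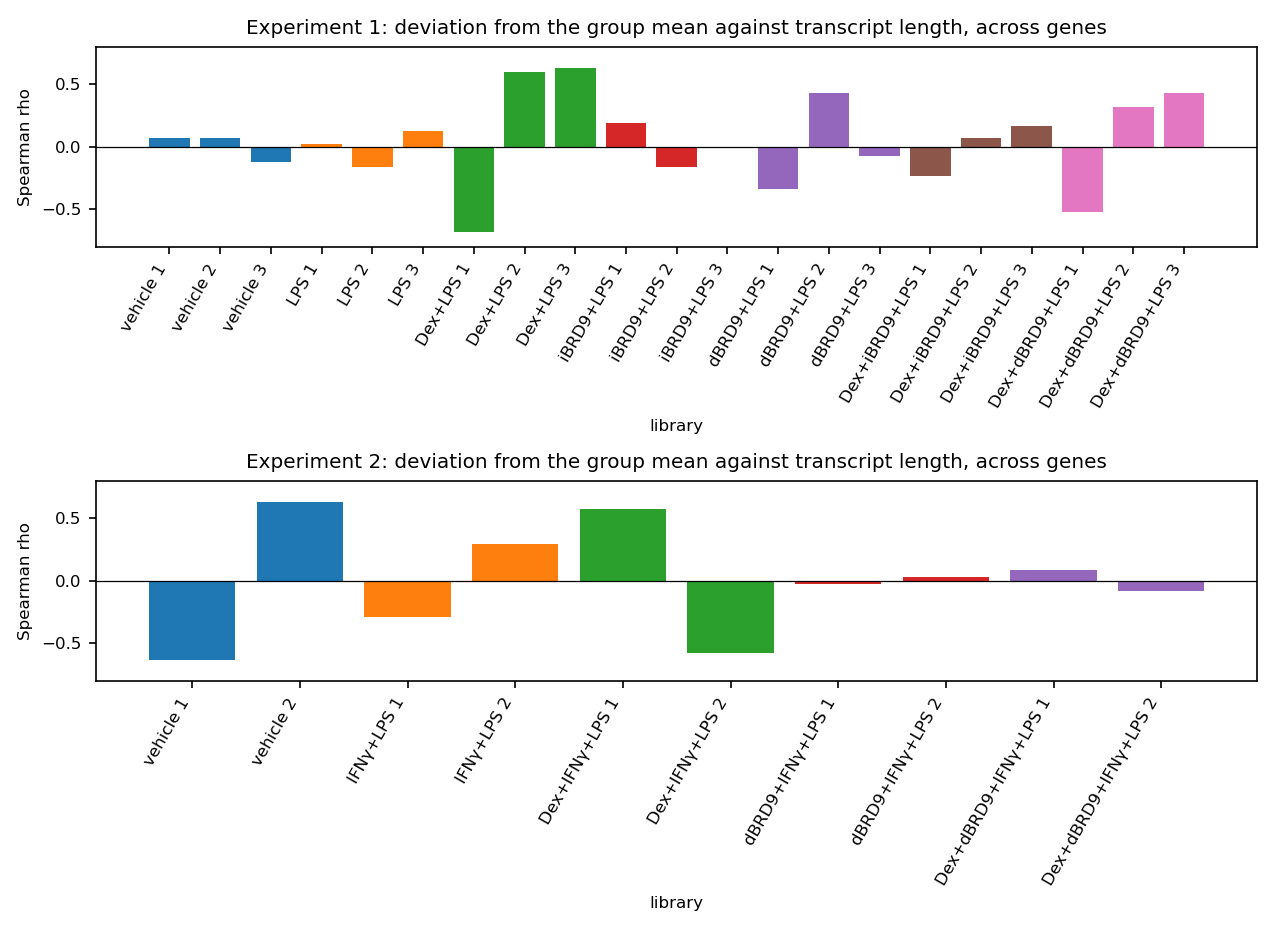
Spearman correlation, across genes, of each library's deviation from its group's mean log2 CPM with transcript length (y axis, rho, no unit; x axis, the libraries, coloured by group, experiment 1 above and experiment 2 below). The first Dex + LPS library (-0.683) and the first Dex + dBRD9 + LPS library (-0.52) have the lowest values of experiment 1. They lie opposite to the others of their groups, in part because deviations within a group balance out. With 2 libraries per group the values of experiment 2 mirror each other by construction.

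Brd9 (ENSMUSG00000057649; mm10 chromosome 13, positions 73937811 to 73960895, plus strand, protein coding) encodes the protein that both compounds act on. Its transcript level in experiment 1 was 24.3 counts per M (CPM) ± 0.162 (SD, n = 3) with vehicle, 43.0 ± 3.5 with LPS and 37.7 ± 0.927 with Dex + LPS. It was 25.2 ± 0.194 with iBRD9 + LPS, 35.4 ± 1.31 with dBRD9 + LPS, 30.3 ± 1.02 with Dex + iBRD9 + LPS and 35.7 ± 2.49 with Dex + dBRD9 + LPS. In experiment 2 (n = 2 each) it was 21.4 ± 3.07 with vehicle, 20.5 ± 0.706 with IFNγ + LPS, 22.1 ± 0.719 with Dex, 21.1 ± 4.06 with dBRD9 and 20.6 ± 2.8 with both. Brd9 rose with LPS by 0.82 on the log2 scale (SE 0.062, adjusted p = 3.9e-11) and was lower with iBRD9 than with LPS alone, with a log2 fold change of -0.77 (SE 0.062, adjusted p = 3e-10). Since the compounds act on the protein, transcript levels do not show whether BRD9 was inhibited or lost. Tsc22d3 and Fkbp5, which the glucocorticoid receptor induces, marked the Dex groups. Fkbp5 (mm10 chromosome 17, 28399094 to 28517527) had means of 526 to 539 CPM in the 3 Dex groups of experiment 1 and of 13.6 to 35.7 CPM in the others. In experiment 2 the values were 286 and 324 CPM against 6.32 to 13.4 CPM.

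**Figure D2:**
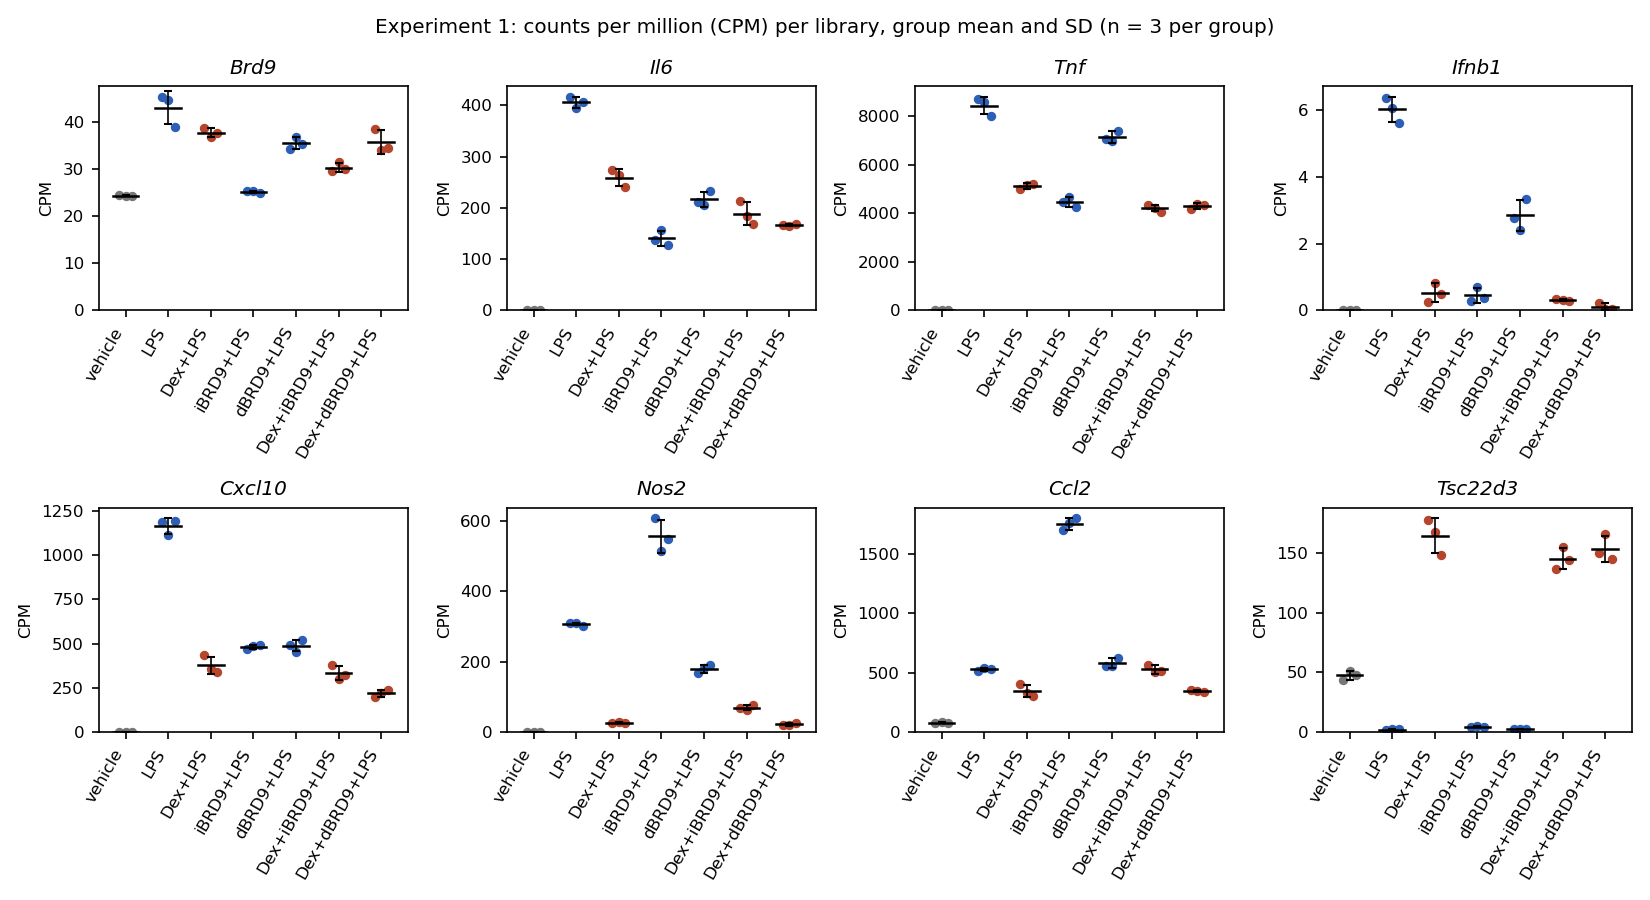
CPM (y axis, linear from 0) of 8 genes in each library of experiment 1, by group (x axis); points are libraries, bars the mean and SD of 3, with grey for vehicle, blue for groups without Dex and red for groups with Dex. Il6, for example, had 406 CPM with LPS, 141 with iBRD9 + LPS and 189 with Dex + iBRD9 + LPS, and Nos2 had 307, 557 and 68.9.

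LPS against vehicle gives the response that the compounds were set against. Genes of cytokines and chemokines rose most: Il6, the gene of interleukin 6 (ENSMUSG00000025746; mm10 chromosome 5, 30013114 to 30019981), had no read in any vehicle library and 406 CPM ± 10.9 (SD, n = 3) with LPS, at least 12000-fold higher. Il12b, the gene of the p40 chain of interleukin 12, went from no read to 126 CPM ± 4.33, at least 3720-fold higher, and Ifnb1, the gene of interferon beta, from no read to 6.01 CPM ± 0.382, at least 178-fold higher. Cxcl3 had 1 read over the vehicle libraries, which gave a ratio of 104000 (95% counting interval 18600 to 4100000). Il1b and Il1a, genes of both interleukin 1 forms, rose by 13.5 (SE 0.1) and 13.3 (SE 0.19) on the log2 scale, and Tnf rose by 8.15 (SE 0.062). All 31 tested members of the inflammatory cytokine list rose (31 adjusted over the list alone, median log2 fold change 8.15, or 7.86 with unread genes at their bound, adjusted p = 1e-04 with an estimated correlation). All 32 tested NF-κB subunits, inhibitors and targets rose (32 adjusted over the list alone, median 3.72, adjusted p = 7.6e-07 with an estimated correlation), among them Cd40 (9.48, SE 0.092) and Tnfaip3 (6.04, SE 0.09), which encodes a brake on NF-κB. The type I interferon response list rose in all 57 members (57 adjusted over the list alone, median 3.07, adjusted p = 0.034 with an estimated correlation), with Rsad2 at 7.75 (SE 0.14) and Ifit1 at 7.41 (SE 0.13). Of 15 interferon-inducible GTPases, which act against intracellular pathogens, 14 rose and 1 fell (14 and 1 adjusted over the list alone, median 4.13, adjusted p = 0.004 with an estimated correlation). Cell cycle genes had 34 lower and 3 higher of 38 (34 and 3 adjusted over the list alone, median -0.85). This list call was lost with an estimated correlation (adjusted p = 0.15). Cxcr4, a chemokine receptor gene, and Cnr2, a cannabinoid receptor gene, had the largest falls (-6.97, SE 0.17, and -6.65, SE 0.15). In all, 4567 genes were higher and 4971 lower, and 1872 and 2300 of them differed at least 2-fold. With library totals alone in place of TMM factors the median of all genes moved from -0.0484 to -0.562 and the split to 2421 higher and 8125 lower, and 795 of the genes called with both scalings changed direction.

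Dex + LPS against LPS shows how the glucocorticoid changed the LPS response. Known glucocorticoid targets rose, with Tsc22d3 (mm10 chromosome X, 140539528 to 140600659) at 165 CPM ± 14.6 (SD, n = 3) against 2.03 ± 0.356, Per1 up by 3.01 (SE 0.067) and Dusp1, the gene of a MAP kinase phosphatase, up by 2.88 (SE 0.05) on the log2 scale. Of 27 tested members of that list 20 rose and 4 fell (20 and 4 adjusted over the list alone, median 1.53, adjusted p = 2.1e-06 with an estimated correlation), among them Cd163, a scavenger receptor gene (4.32, SE 0.17), and Mt2 (3.79, SE 0.074). Of the 31 cytokine genes 26 fell and 2 rose (27 and 2 adjusted over the list alone, median -0.81, adjusted p = 0.026 with an estimated correlation). Ptgs2, which encodes a prostaglandin synthase, fell by 4.12 (SE 0.11). Nos2, the gene of inducible nitric oxide synthase (-3.55, SE 0.1), Ccl22 (-5.16, SE 0.13) and Il1b (-2.09, SE 0.056) fell as well, and Il6 (-0.65, SE 0.079) and Tnf (-0.72, SE 0.045) fell less. Ifnb1 fell by 3.55 (SE 0.29), to 0.529 CPM. Of 57 type I interferon genes 56 fell and 1 rose (56 and 1 adjusted over the list alone, median -1.48, adjusted p = 0.039 with an estimated correlation), including Mx1 (-3.19, SE 0.14) and Ifit2 (-3.04, SE 0.13). All 15 interferon-inducible GTPases fell (15 adjusted over the list alone, median -1.87, adjusted p = 0.026 with an estimated correlation). In the antigen presentation list 20 of 25 fell and 1 rose (20 and 1 adjusted over the list alone, adjusted p = 0.042 with an estimated correlation), led by the class II genes H2-Aa (-4.44, SE 0.14) and H2-Eb1 (-4.21, SE 0.11) and their activator Ciita (-3.89, SE 0.14). Cholesterol synthesis genes fell in 22 of 24 (22 adjusted over the list alone, median -1.32, adjusted p = 0.028 with an estimated correlation), with Cyp51 at -2.15 (SE 0.077). Cell cycle genes fell in 32 of 38 (32 adjusted over the list alone, median -0.80, adjusted p = 0.031 with an estimated correlation). The genes with the largest rise were Jaml (8.07, SE 0.27), Tsc22d3 (6.33, SE 0.11) and Tns1 (6.01, SE 0.11), and Inhba (-5.60, SE 0.23), the gene of an activin subunit, was among those with the largest fall. In all, 3531 genes were higher and 3485 lower, 690 and 1164 of them at least 2-fold, and the split with library totals alone was 4364 higher and 2947 lower.

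iBRD9 + LPS against LPS shows what the bromodomain inhibitor did to the LPS response. Genes of the interferon pathway fell: Ifnb1 (ENSMUSG00000048806; mm10 chromosome 4, 88522025 to 88522774) dropped by 3.75 on the log2 scale (SE 0.29), from 6.01 to 0.454 CPM. All 57 type I interferon genes were lower (57 adjusted over the list alone, median -1.91, adjusted p = 0.012 with an estimated correlation), such as Mx1 (-3.88, SE 0.15) and Oasl1 (-3.60, SE 0.12). Cytokine genes moved both ways. Il6 (-1.53, SE 0.081), Tnf (-0.92, SE 0.045), Cxcl10 (-1.27, SE 0.091) and Il12a (-3.79, SE 0.14) fell. Ccl2, the gene of a monocyte-attracting chemokine, rose by 1.73 (SE 0.076), from 528 to 1754 CPM, and Nos2 (0.86, SE 0.089) and Il12b (0.73, SE 0.069) rose too. In that list 19 of 31 fell and 6 rose (19 and 7 adjusted over the list alone). An estimated correlation took this call away (adjusted p = 0.44). Of the 15 GTPases 10 fell and 4 rose (10 and 4 adjusted over the list alone, median -1.83, adjusted p = 0.073 with an estimated correlation, so the call was lost). Antigen presentation genes had 19 of 25 lower and 3 higher (19 and 3 adjusted over the list alone, adjusted p = 0.17 with an estimated correlation), led by H2-Eb1 (-4.27, SE 0.11). Cell cycle genes fell in 35 of 38 and 1 rose (35 and 1 adjusted over the list alone, median -1.79, adjusted p = 0.0024 with an estimated correlation), with Cdc20 at -2.76 (SE 0.12) and Ccna2 at -2.68 (SE 0.14). Of 16 markers of alternative activation 13 fell (13 adjusted over the list alone, median -1.29, adjusted p = 0.012 with an estimated correlation), among them the transcription factor gene Irf4 (-2.94, SE 0.18) and the folate receptor gene Folr2 (-1.95, SE 0.094). Among the large falls was Ccr3 at -5.82 (SE 0.21). Ccr2, which lay under 10 CPM and is named outside the rule for named genes, was at least 89.9-fold lower. It had 235 reads over the LPS libraries and was unread in all 3 libraries with iBRD9 + LPS. The genes with the largest rise were Snx30 (2.94, SE 0.12) and the kinase gene Mknk2 (2.82, SE 0.08). Glucocorticoid targets had 9 higher and 12 lower of 27 (10 and 12 adjusted over the list alone, adjusted p = 0.44 with an estimated correlation). In all, 3979 genes were higher and 3865 lower, 739 and 1602 of them at least 2-fold. With library totals alone the median of all genes moved from 0.0104 to 0.144 and the split to 5193 higher and 3032 lower.

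dBRD9 + LPS against LPS asks the same of the degrader. The interferon pathway was lower again: Ifnb1 fell by 1.08 (SE 0.22), to 2.84 CPM. In the type I interferon list 50 of 57 genes fell with none called higher (55 adjusted over the list alone, median -0.60, adjusted p = 0.041 with an estimated correlation), with Oasl1 at -1.89 (SE 0.11) and Mx1 at -1.40 (SE 0.13). Of the 15 GTPases 11 fell (12 adjusted over the list alone, with 2 higher; median -0.97, adjusted p = 0.017 with an estimated correlation), with Iigp1 at -2.15 (SE 0.15) and Ifi47 at -1.55 (SE 0.11). Il6 fell by 0.90 (SE 0.079), from 406 to 217 CPM, and Cxcl10 (-1.25, SE 0.091), Nos2 (-0.78, SE 0.09) and Tnf (-0.24, SE 0.045) fell too. Il12b rose by 0.57 (SE 0.069) and Il1b by 0.26 (SE 0.054). Cytokine genes had 13 of 31 lower and 7 higher (14 and 7 adjusted over the list alone). This call was lost with an estimated correlation (adjusted p = 0.5). Cell cycle genes fell in 19 of 38 (22 adjusted over the list alone, median -0.31, adjusted p = 0.041 with an estimated correlation), such as Mcm7 (-0.58, SE 0.091). Of 27 glucocorticoid targets 10 fell and 3 rose (10 and 6 adjusted over the list alone, median -0.06, adjusted p = 0.041 with an estimated correlation), with Fpr1, the gene of a formyl peptide receptor, at -2.75 (SE 0.18) and the scavenger receptor gene Stab1 at -1.19 (SE 0.079). Pdgfb, a growth factor gene, had the largest rise (1.15, SE 0.076). Bicral, the gene of another subunit of the non-canonical BAF complex, rose by 0.99 (SE 0.097). In all, 841 genes were higher and 1262 lower, 29 and 253 of them at least 2-fold, and the split with library totals alone was 1402 higher and 1039 lower. The count was 3465 without both libraries that stood apart, although neither is in the compared groups, and 3305 when only these 2 groups were fitted.

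iBRD9 + LPS against dBRD9 + LPS tests where the compounds differed, at doses that differ or are not known. Nos2 was 1.64 higher on the log2 scale with iBRD9 (SE 0.091; 95% interval 1.45 to 1.83) and Ccl2 1.60 higher (SE 0.076; 1.44 to 1.75). Ifnb1 was lower (-2.66, SE 0.31; -3.32 to -2.01), as were Tnf (-0.67, SE 0.045), Il6 (-0.63, SE 0.08) and Il1b (-0.50, SE 0.054). Cxcl10 was not shown to differ, with -0.02 and a 95% interval of -0.207 to 0.165 (adjusted p = 0.86), nor was Il12b, with 0.16 and an interval of 0.0161 to 0.301 (adjusted p = 0.056, but 0.00407 to 0.0252 in the settings that call it, among them library totals alone and limma voom). All 57 type I interferon genes were lower with iBRD9 (57 adjusted over the list alone, median -1.24). This list call was lost with an estimated correlation (adjusted p = 0.061). Cell cycle genes were lower in 33 of 38 and higher in 1 (33 and 1 adjusted over the list alone, median -1.45, adjusted p = 0.0016 with an estimated correlation), with Kif11 at -2.11 (SE 0.13). Markers of alternative activation were lower in 10 of 16 (10 adjusted over the list alone, median -0.99, adjusted p = 0.02 with an estimated correlation), with Irf4 at -3.10 (SE 0.18). Tgfbi (-5.78, SE 0.13) was the gene with the lowest value, followed by Serpinb9b (-5.27, SE 0.18), and Snx30 (2.83, SE 0.12) and the chemokine gene Ccl7 (2.76, SE 0.087) had the highest. In all, 3584 genes were higher and 3450 lower, 552 and 1224 of them at least 2-fold, and the split with library totals alone was 4341 higher and 2885 lower. Each compound's fold changes over LPS correlated across 12662 genes (Pearson r 0.555, Spearman rho 0.526). Draws with shared controls and no effect of either compound gave a mean r of 0.51 (0.464 to 0.563). Their r comes from noise alone, so it does not measure how much of 0.555 is due to shared controls. The covariance was 0.252, against a mean of 0.0323 in the draws. Both compounds lowered 1087 genes (385 expected by chance) and raised 553 (264 expected), and 187 went opposite ways (55 up and 132 down with iBRD9, 397 and 257 expected). These expected numbers assume independent comparisons. Shared controls favour calls in the same direction, so they are not a full chance level. At most 1 gene was called for both in the 100 draws, which was fixed in advance, since they hold no effect of either compound.

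Dex + iBRD9 + LPS against Dex + LPS asks what the inhibitor added when the glucocorticoid was present. Nos2 rose by 1.40 (SE 0.1), from 26.2 to 68.9 CPM, and Ccl2 by 0.62 (SE 0.075), while Il6 (-0.46, SE 0.079), Tnf (-0.28, SE 0.045) and Ptgs2 (-0.88, SE 0.1) fell. Ifnb1 was at 0.314 against 0.529 CPM, -0.70 (SE 0.49, adjusted p = 0.29). Type I interferon genes had 16 of 57 lower and 5 higher (16 and 5 adjusted over the list alone, median -0.12, adjusted p = 0.78 with an estimated correlation). GTPases moved both ways, with 5 of 15 higher and 4 lower (5 and 5 adjusted over the list alone, median -0.19 but a test in the upward direction, adjusted p = 0.55 with an estimated correlation), such as Gbp7 (1.25, SE 0.11) and Gbp3 (0.95, SE 0.06). Cytokine genes had 16 of 31 lower and 4 higher (16 and 4 adjusted over the list alone). With an estimated correlation this call was lost (adjusted p = 0.63). Of 27 glucocorticoid targets 12 fell and 4 rose (13 and 4 adjusted over the list alone, median -0.22, adjusted p = 0.046 with an estimated correlation), with Fpr1 at -2.58 (SE 0.16), Thbs1 at -2.05 (SE 0.15) and the kinase gene Sgk1 at -0.90 (SE 0.068). Fkbp5 (-0.03, SE 0.051), Tsc22d3 (-0.18, SE 0.073) and Per1 (0.03, SE 0.057) were not called, and Dusp1 fell by 0.22 (SE 0.046). Some settings called Tsc22d3, among them DESeq2 and limma voom (adjusted p = 0.0121 to 0.0411), and removing the length trend called Fkbp5 (0.0465). Markers of alternative activation fell in 11 of 16 and rose in 1 (11 and 1 adjusted over the list alone, median -0.68, adjusted p = 0.001 with an estimated correlation), with F13a1, a coagulation factor gene of macrophages, at -2.85 (SE 0.1) and the lectin genes Chil3 and Clec10a at -1.71 (SE 0.1) and -1.56 (SE 0.18). Siglec1 (-2.99, SE 0.2) and Cbr2 (-2.91, SE 0.16) had the largest falls. In all, 2110 genes were higher and 2280 lower, 144 and 409 of them at least 2-fold, and the split with library totals alone was 3089 higher and 1656 lower. A fit of these 2 groups alone called 2283 genes.

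Dex + dBRD9 + LPS against Dex + LPS asks the same of the degrader. Il6 (-0.64, SE 0.08), Cxcl10 (-0.79, SE 0.091), Ptgs2 (-0.71, SE 0.1) and Tnf (-0.25, SE 0.045) fell. Ifnb1 fell by 2.14 (SE 0.58), at 0.106 against 0.529 CPM, a call lost without the second Dex + LPS library (adjusted p = 0.0735) and without replicate 2 or 3 of Dex + dBRD9 + LPS (0.0796 and 0.0655). Il1b, Il12b, Nos2 and Ccl2 were not called, with log2 values of 0.00466 (SE 0.054), -0.07 (SE 0.076), -0.27 (SE 0.11) and 0.01 (SE 0.075), but Nos2 was called in some settings, among them DESeq2 (adjusted p = 0.00324 to 0.0485). Of 27 glucocorticoid targets 11 fell and 1 rose (13 and 1 adjusted over the list alone, median -0.21, adjusted p = 0.0017 with an estimated correlation), with Fpr1 at -3.08 (SE 0.16), Stab1 at -2.32 (SE 0.081), Sgk1 at -1.10 (SE 0.068) and Cebpd at -0.68 (SE 0.083). Fkbp5, Tsc22d3, Dusp1 and Per1 were not called, at -0.03 (SE 0.051), -0.10 (SE 0.073), -0.03 (SE 0.046) and 0.03 (SE 0.057). Markers of alternative activation fell in 9 of 16 and rose in 2 (10 and 2 adjusted over the list alone, median -0.28, adjusted p = 0.013 with an estimated correlation), with F13a1 at -2.38 (SE 0.1) and Tgm2 at -1.20 (SE 0.072). In the type I interferon list 22 of 57 were lower and 1 was higher (29 and 2 adjusted over the list alone, median -0.24). An estimated correlation took this call away (adjusted p = 0.29). GTPases had 7 of 15 lower and 2 higher (8 and 2 adjusted over the list alone, adjusted p = 0.16 with an estimated correlation, so lost too). The list of cytokines had 13 of 31 lower and 4 higher (17 and 4 adjusted over the list alone, lost, adjusted p = 0.16 with an estimated correlation). Cbr2 (-2.91, SE 0.16) and Siglec1 (-2.39, SE 0.18) fell, and Bicral (1.33, SE 0.093), the innate receptor gene Trem1 (1.30, SE 0.17) and Tlr9 (1.23, SE 0.12) rose. In all, 824 genes were higher and 1175 lower, 42 and 193 of them at least 2-fold, and the split with library totals alone was 1598 higher and 843 lower. A fit of these 2 groups alone, each of which holds a library that stood apart, called 142 higher and 437 lower.

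Under Dex the compounds were again compared directly, as Dex + iBRD9 + LPS against Dex + dBRD9 + LPS, with the same limit on doses. Nos2 was 1.67 higher with iBRD9 (SE 0.1; 95% interval 1.46 to 1.88), Cxcl10 0.61 higher (SE 0.091; 0.424 to 0.801), Ccl2 0.60 higher (SE 0.075; 0.449 to 0.76) and Ccl7 1.17 higher (SE 0.088). Il6 and Tnf were not shown to differ, with 0.18 (95% interval 0.0176 to 0.348, adjusted p = 0.13) and -0.03 (-0.121 to 0.0637, adjusted p = 0.73), nor was Fkbp5 (-0.104 to 0.108, adjusted p = 0.99). GTPases were higher in 9 of 15 with iBRD9 (9 adjusted over the list alone, median 0.58, adjusted p = 0.011 with an estimated correlation), with Gbp3 at 0.91 (SE 0.06) and Gbp7 at 0.86 (SE 0.11). For type I interferon genes 14 of 57 were higher and 3 lower (17 and 4 adjusted over the list alone, median 0.13). This call was lost with an estimated correlation (adjusted p = 0.56). Markers of alternative activation were lower in 10 of 16 and higher in 1 (11 and 3 adjusted over the list alone, median -0.39, adjusted p = 0.011 with an estimated correlation), with Chil3 at -1.12 (SE 0.1). Net1 (-1.54, SE 0.12) and Clec4n (-1.43, SE 0.12) were among the lowest. In all, 877 genes were higher and 1145 lower, 35 and 115 of them at least 2-fold. Fold changes over Dex + LPS correlated across genes (r 0.67, rho 0.672). The draws with shared controls and no effect of either compound had a mean r of 0.505 (0.453 to 0.549), again from noise alone. The covariance was 0.167, against a mean of 0.0376 in the draws. Both compounds lowered 962 genes (212 expected by chance) and raised 571 (137 expected), and 32 went opposite ways (9 up and 23 down with iBRD9, 196 and 148 expected). The expected numbers again assume independent comparisons, which shared controls do not give. Without the third Dex + iBRD9 + LPS library the direct comparison called 1281 genes.

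**Figure D3:**
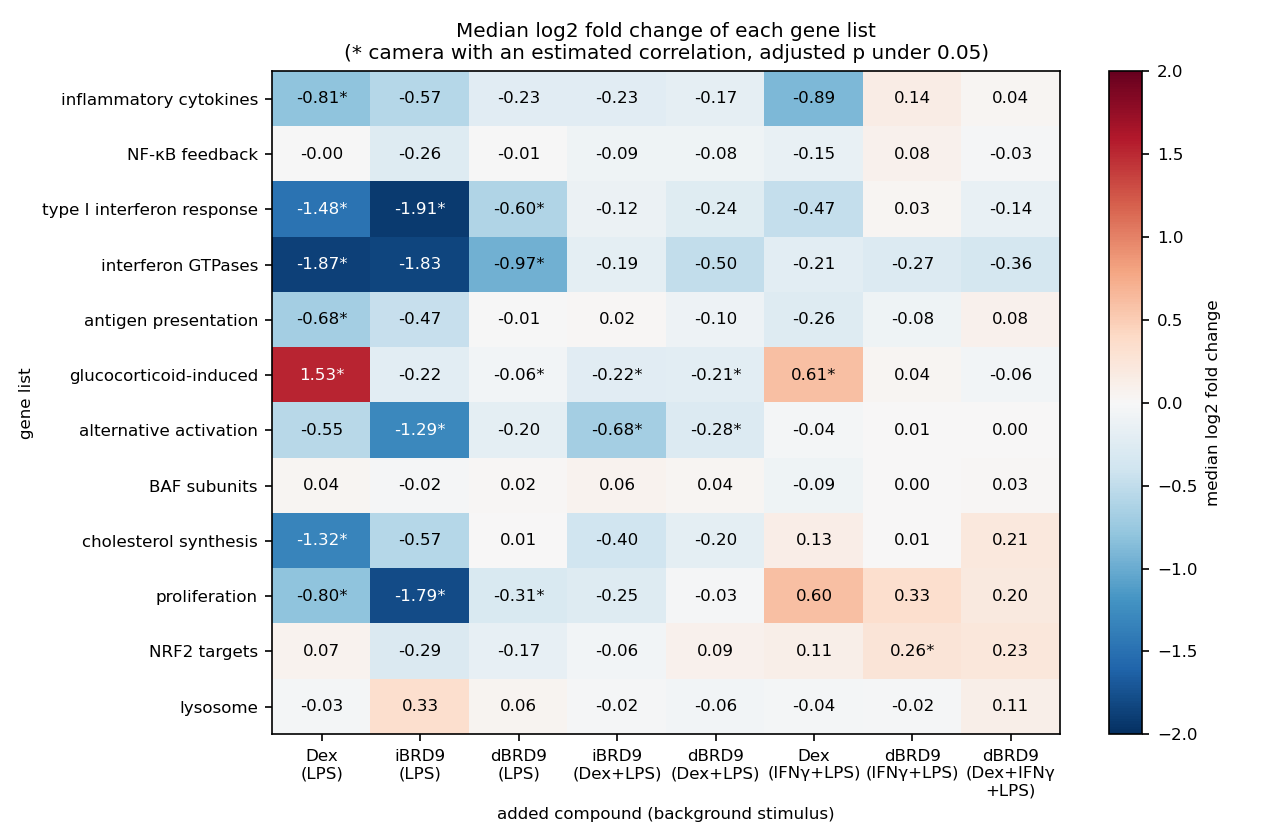
Median log2 fold change of 12 gene lists (y axis) in 8 comparisons (x axis), with the value in each cell and colour from blue (lower) to red (higher); an asterisk marks an adjusted p under 0.05 with an estimated correlation. The type I interferon list had -1.91 with iBRD9 and -0.60 with dBRD9 without Dex, and -0.12 and -0.24 with Dex.

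The interaction of Dex and iBRD9 tests whether the inhibitor's effect differed with the glucocorticoid present; a positive value means that iBRD9 lowered a gene less, or raised it more, with Dex. All 57 type I interferon genes had positive values that passed (57 adjusted over the list alone, median 1.77, adjusted p = 0.0019 with an estimated correlation), with Mx1 at 3.22 (SE 0.2) and Ifit3b at 3.58 (SE 0.27). Ifnb1 itself had 3.05 (SE 0.63, adjusted p = 0.00077). GTPases had 14 of 15 positive (14 adjusted over the list alone, median 1.89, adjusted p = 0.0022 with an estimated correlation), led by Iigp1 (3.34, SE 0.29). Among cytokine and effector genes, Il6 had 1.07 (SE 0.11), Cxcl10 1.09 (SE 0.13), Tnf 0.64 (SE 0.063), Nos2 0.53 (SE 0.13), Il12b -0.77 (SE 0.1) and Ccl2 -1.12 (SE 0.11). Il1b (0.05, SE 0.076) and Ptgs2 (0.14, SE 0.14) were not called. In the cytokine list 13 of 31 were positive and 8 negative (13 and 8 adjusted over the list alone). With an estimated correlation this call was lost (adjusted p = 0.59). Cell cycle genes were positive in 29 of 38 and negative in 1 (31 and 1 adjusted over the list alone, median 1.21, adjusted p = 0.00054 with an estimated correlation), with Bub1b at 2.69 (SE 0.13). Lysosome genes were negative in 18 of 25 (21 adjusted over the list alone, median -0.32, adjusted p = 0.0097 with an estimated correlation), with Neu1 at -0.78 (SE 0.081). Glucocorticoid targets went both ways, with 10 of 27 positive and 9 negative (10 and 10 adjusted over the list alone, adjusted p = 0.96 with an estimated correlation): Tsc22d3 had -1.25 (SE 0.17), Per1 -0.96 (SE 0.091), Dusp1 -0.67 (SE 0.066) and Fkbp5 -0.39 (SE 0.077). Those 4 rose with iBRD9 in LPS alone, by 1.07, 0.99, 0.45 and 0.36, and had -0.18, 0.03, -0.22 and -0.03 under Dex. The highest values were those of Col15a1 (4.83, SE 0.36) and the fractalkine receptor gene Cx3cr1 (4.73, SE 0.46), and the lowest those of Prss16 (-2.88, SE 0.27) and P4ha2 (-2.22, SE 0.18). In all, 2186 genes were positive and 2024 negative, 935 and 219 of them at least 2-fold, and the split with library totals alone was 1934 positive and 2486 negative.

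**Figure D4:**
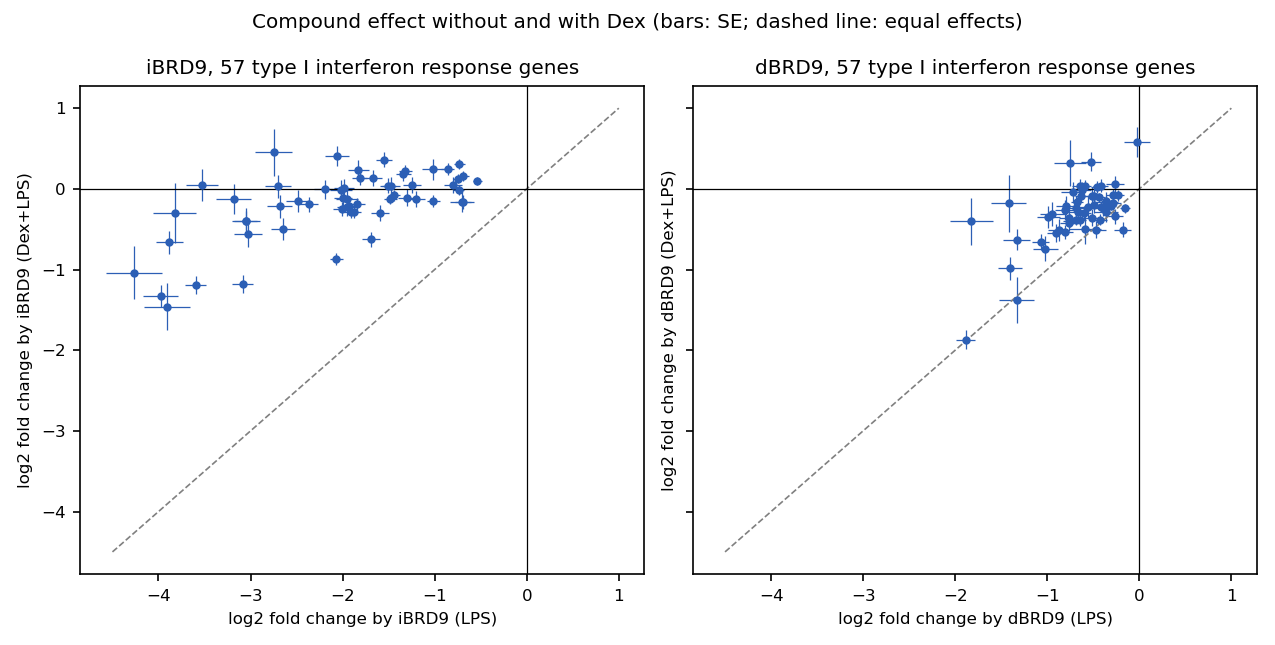
Log2 fold change of the 57 type I interferon genes caused by each compound without Dex (x axis) and with Dex (y axis), iBRD9 on the left and dBRD9 on the right; bars are SEs and the dashed line marks equal effects. With iBRD9 the genes lay between -4.26 and -0.54 without Dex and between -1.46 and 0.46 with Dex; with dBRD9 the ranges were -1.89 to -0.03 and -1.87 to 0.58.

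The interaction of Dex and dBRD9 was called in fewer genes. Il12b had -0.64 (SE 0.1), Nos2 0.50 (SE 0.14, adjusted p = 0.044) and Cxcl10 0.46 (SE 0.13, adjusted p = 0.046), while Il6 (0.27, SE 0.11), Tnf (-0.00884, SE 0.063) and Ifnb1 (-1.05, SE 0.64) were not called. The calls of Nos2 and Cxcl10 were lost with DESeq2 size factors (adjusted p = 0.056 and 0.0576) and without any of the LPS or dBRD9 + LPS libraries (0.0562 to 0.116 and 0.0613 to 0.134). Both were also lost without the third library of Dex + LPS (0.0694 and 0.0948) or of Dex + dBRD9 + LPS (0.178 and 0.149), and that of Cxcl10 without the second of each (0.0878 and 0.108). Without both libraries that stood apart Il6 and Ifnb1 were called (0.0495 and 0.0462). Type I interferon genes had 13 of 57 positive (30 adjusted over the list alone, with 1 negative; median 0.34). This list call was lost with an estimated correlation (adjusted p = 0.19). A called member was Oas3 at 0.86 (SE 0.16). NRF2 antioxidant targets had 8 of 20 positive (9 adjusted over the list alone, lost, adjusted p = 0.19 with an estimated correlation). Of 27 glucocorticoid targets 3 were positive and 4 negative (4 and 7 adjusted over the list alone, adjusted p = 0.24 with an estimated correlation), with Stab1 at -1.14 (SE 0.11) and Thbs1 at 0.85 (SE 0.17). Saa3, an acute phase gene (1.41, SE 0.11), and Tnfsf10 (1.63, SE 0.24) were high, and Ccl17 (-1.96, SE 0.23) and Cbr2 (-1.62, SE 0.38) were low, with the call of Cbr2 lost by limma voom (adjusted p = 0.0505) and without the first or the second dBRD9 + LPS library (0.0909 and 0.0726). In all, 230 genes were positive and 199 negative, 23 and 11 of them at least 2-fold. The count was 947 without both libraries that stood apart and 890 without the Dex + LPS library among them, and it was 269, 266 and 271 without the first LPS, the third LPS and the second Dex + dBRD9 + LPS library.

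IFNγ + LPS against vehicle gives the stimulation that experiment 2 started from. Il12b went from no read to 583 CPM ± 19.2 (SD, n = 2), at least 8400-fold higher. Nos2 (ENSMUSG00000020826; mm10 chromosome 11, 78920787 to 78960254), with 3 reads over the vehicle libraries, reached 3790 CPM ± 77.7, a ratio of 54500 (95% counting interval 18600 to 264000). Cxcl9, a chemokine gene induced by IFNγ, rose by 15.0 on the log2 scale (SE 0.24), and Steap4 was at least 2230-fold higher. All 19 interferon-inducible GTPases rose (19 adjusted over the list alone, median 7.58, or 6.80 with unread genes at their bound, adjusted p = 0.011 with an estimated correlation), as did all 57 type I interferon genes (57 adjusted over the list alone, median 4.24, adjusted p = 0.0088 with an estimated correlation) and all 32 NF-κB genes (32 adjusted over the list alone, median 3.89, adjusted p = 0.00028 with an estimated correlation). Cytokine genes rose in 28 of 30 (28 adjusted over the list alone, median 6.79, or 6.33 with bounds, adjusted p = 0.0088 with an estimated correlation). Antigen presentation genes rose in 21 of 24 (21 adjusted over the list alone). An estimated correlation took this call away (adjusted p = 0.43). A called member was Ciita at 5.69 (SE 0.29). Glycolysis genes rose in 16 of 23 and fell in 3 (16 and 3 adjusted over the list alone, lost, adjusted p = 0.091 with an estimated correlation), with Hk2, the gene of a hexokinase, at 4.88 (SE 0.14). Cd300lb (-6.78, SE 0.21) and Lyl1 (-6.21, SE 0.2) were among the largest falls. In all, 4371 genes were higher and 4745 lower, 2793 and 2755 of them at least 2-fold. With library totals alone the median of all genes moved from -0.11 to -0.758 and the split to 2632 higher and 7819 lower, and 183 of the genes called with both scalings changed direction.

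Dex + IFNγ + LPS against IFNγ + LPS asks how the glucocorticoid changed that response. Il1b fell by 3.90 (SE 0.14), from 1240 to 83.4 CPM, and Il12b (-3.31, SE 0.14), Ptgs2 (-2.37, SE 0.15), Il6 (-2.01, SE 0.16) and Ifnb1 (-3.98, SE 0.49) fell too. Tnf (-0.42, SE 0.1) and Nos2 (-0.42, SE 0.12) fell less, and Cxcl10 had 0.04 (SE 0.12, adjusted p = 0.85). Cytokine genes had 19 of 30 lower and 5 higher (20 and 5 adjusted over the list alone, median -0.89). This call was lost with an estimated correlation (adjusted p = 0.072). Glucocorticoid targets rose in 12 of 27 and fell in 1 (12 and 1 adjusted over the list alone, median 0.61, adjusted p = 0.0011 with an estimated correlation), with Tsc22d3 up by 6.72 (SE 0.15), Fkbp5 by 4.59 (SE 0.12), Per1 by 4.38 (SE 0.21) and Mt2 by 3.98 (SE 0.19). The type I interferon list fell in 39 of 57 (45 adjusted over the list alone, median -0.47), lost with an estimated correlation (adjusted p = 0.11), with Mx1 at -1.62 (SE 0.12). GTPases had 7 of 19 lower and 2 higher (8 and 2 adjusted over the list alone, lost, adjusted p = 0.57 with an estimated correlation). Cell cycle genes, which fell with Dex in experiment 1, had 12 of 38 higher and 1 lower (16 and 1 adjusted over the list alone, median 0.60, lost, adjusted p = 0.53 with an estimated correlation). Cholesterol synthesis genes had 4 of 23 higher and 1 lower (4 and 2 adjusted over the list alone, adjusted p = 0.75 with an estimated correlation). Tns1 (5.96, SE 0.22) and Saa3 (5.12, SE 0.18) rose, and the potassium channel gene Kcna3 (-5.08, SE 0.45) and the cytokine gene Lif (-4.07, SE 0.34) fell. In all, 1429 genes were higher and 1226 lower, 554 and 348 of them at least 2-fold, and the split with library totals alone was 1703 higher and 944 lower. The count was 1549 and 1530 without the first and the second IFNγ + LPS library. The call of Nos2 was lost without either of them (adjusted p = 0.0719 and 0.109) and without the second Dex library (0.2), and that of Tnf without the second IFNγ + LPS library (0.0668).

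**Figure D5:**
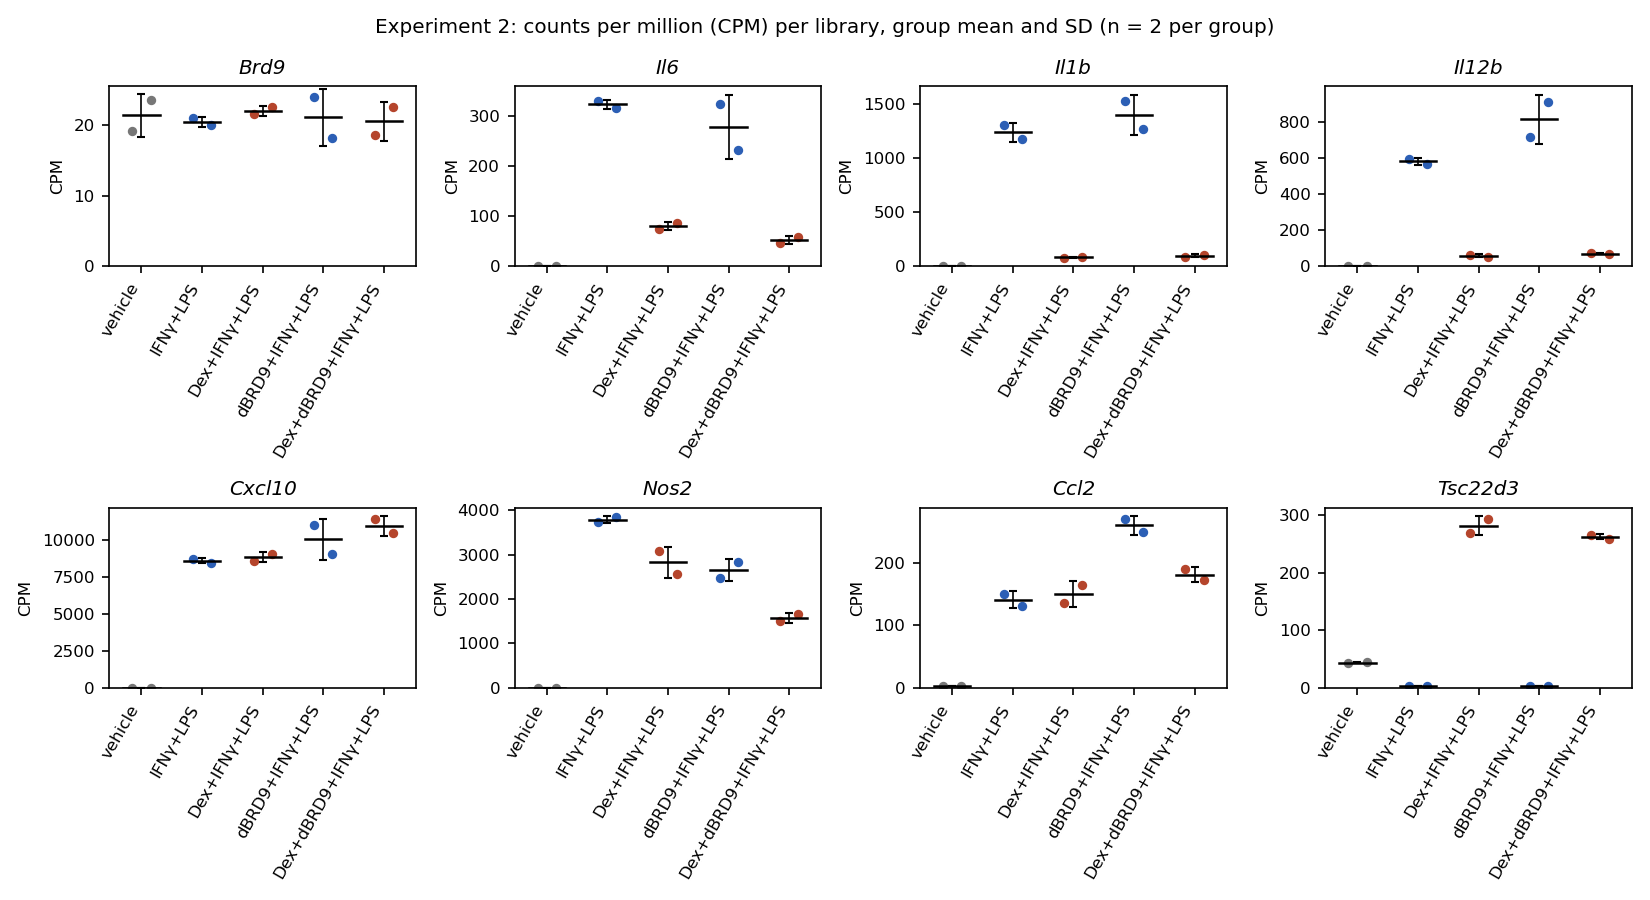
CPM (y axis, linear from 0) of 8 genes in each library of experiment 2, by group (x axis); points are libraries, bars the mean and SD of 2, with grey for vehicle, blue for groups without Dex and red for groups with Dex. Nos2 had 3790 CPM with IFNγ + LPS, 2660 with dBRD9, 2830 with Dex and 1580 with both.

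dBRD9 + IFNγ + LPS against IFNγ + LPS asks what the degrader did in this stimulation. Nos2 fell by 0.51 (SE 0.12, adjusted p = 0.036), from 3790 to 2660 CPM, and Ccl2 rose by 0.88 (SE 0.12, adjusted p = 0.00056), from 141 to 260 CPM. Il6 (-0.22, SE 0.15), Tnf (0.25, SE 0.1), Il12b (0.48, SE 0.12), Ifnb1 (-0.73, SE 0.35) and Cxcl10 (0.23, SE 0.12) were not called. Of 19 interferon-inducible GTPases 5 fell and none rose (10 adjusted over the list alone, median -0.27). With an estimated correlation this call was lost (adjusted p = 0.091). Among its members were Tgtp1 at -2.09 (SE 0.11; 35.6 against 152 CPM) and Gbp6 at -1.51 (SE 0.12). Type I interferon genes had 3 of 57 higher and 4 lower (9 and 6 adjusted over the list alone, median 0.03 but a test in the downward direction, adjusted p = 0.98 with an estimated correlation), with Slfn4 at -1.39 (SE 0.14). Cytokine genes had 4 of 30 higher and 1 lower (8 and 3 adjusted over the list alone, lost, adjusted p = 0.38 with an estimated correlation). NRF2 antioxidant targets rose in 4 of 20 (6 adjusted over the list alone, median 0.26, adjusted p = 0.036 with an estimated correlation), with the heme oxygenase gene Hmox1 at 0.81 (SE 0.1). In experiment 1 the summed CPM of that list was lower with dBRD9 + LPS than with LPS (38490 CPM ± 713 against 42410 ± 852, SD, n = 3). A sum weights members by their abundance and a median does not, so these values do not show opposite effects in the experiments. Cell cycle genes had 1 of 38 higher (1 adjusted over the list alone, median 0.33, where it was -0.31 in experiment 1, lost, adjusted p = 0.38 with an estimated correlation). Lipg (-2.23, SE 0.2) and Cd38, the gene of an NAD hydrolase (-2.10, SE 0.17), had the largest falls and Rgcc (1.43, SE 0.22) the largest rise, a call lost without the first IFNγ + LPS library (adjusted p = 0.0664) or the first with dBRD9 (0.0589). In all, 109 genes were higher and 134 lower, 19 and 52 of them at least 2-fold, and the split with library totals alone was 70 higher and 134 lower. The count was 410 when only these 2 groups were fitted, and 65, 67, 79 and 90 when a library of these groups was left out, where the lone sample left is assumed to vary like the other groups. In each of those 4 fits the call of Nos2 was lost (adjusted p = 0.087 to 0.262), as with the replicate number as a block (0.0786), while some settings called Il12b, among them DESeq2 (0.00625 to 0.0333).

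Dex + dBRD9 + IFNγ + LPS against Dex + IFNγ + LPS asks what the degrader added to the glucocorticoid in this stimulation. Nos2 fell by 0.84 (SE 0.12, adjusted p = 0.0013), from 2830 to 1580 CPM. Il6 (-0.62, SE 0.16, adjusted p = 0.081), Cxcl10 (0.31, SE 0.12), Ccl2 (0.27, SE 0.12), Tsc22d3 (-0.10, SE 0.1) and Fkbp5 (-0.18, SE 0.097) were not called. Of 19 GTPases 4 fell (9 adjusted over the list alone, median -0.36). An estimated correlation took this call away (adjusted p = 0.11). Among its members were Tgtp1 at -2.25 (SE 0.11) and Gbp6 at -1.58 (SE 0.12). Type I interferon genes fell in 5 of 57 (8 adjusted over the list alone, median -0.14; lost, adjusted p = 0.64 with an estimated correlation), with Slfn4 at -1.76 (SE 0.16) and Oasl1 at -0.99 (SE 0.13). Glucocorticoid targets had 1 of 27 lower. Mmp14, the gene of a matrix protease, was among the largest falls (-1.91, SE 0.14). Among the genes that met the rule for named genes, Bicral (1.01, SE 0.24) and Hmox1 (0.78, SE 0.1) had the largest rises. The call of Bicral was lost with library totals alone (adjusted p = 0.066) and with the replicate number as a block (0.0769). It was also lost without the second Dex + IFNγ + LPS library (log2 fold change 0.684) and without either library with dBRD9 (0.999 and 1.018). That of Nos2 was lost without the first library with dBRD9 (-0.766). Some settings called Il6, among them DESeq2 (adjusted p = 0.000366 to 0.0105). In all, 31 genes were higher and 155 lower, 3 and 62 of them at least 2-fold. The count was 511 when only these 2 groups were fitted, and 33, 37 and 65 without the first or the second library with dBRD9 and without the first of Dex + IFNγ + LPS.

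The interaction of Dex and dBRD9 in experiment 2 had a single call by edgeR, against 31 by DESeq2, and 1222 genes had an unadjusted p under 0.05. The gene was A930037H05Rik, an uncharacterized transcript that is named outside the rule for named genes, after its values were seen (-2.31, SE 0.281, adjusted p = 0.00595). It had 11.6 CPM ± 0.279 (SD, n = 2) with IFNγ + LPS, 10.5 ± 3.31 with Dex, 24.6 ± 1.12 with dBRD9 and 4.43 ± 0.135 with both. Ccl2 (-0.61, SE 0.17), Nos2 (-0.33, SE 0.17) and Il6 (-0.40, SE 0.22) were not called, and no gene of any list was. Removing the length trend called Ccl2 (-0.90, adjusted p = 0.00874). The call of A930037H05Rik was lost without any library with dBRD9 (adjusted p = 0.0517 to 0.142). Counts of 0 to 9 came from fits that left out a library, and in a trial with planted changes this comparison recovered 36% of 2-fold changes.

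Between the experiments, which differ in stimulus, depth and group size, effects were set side by side across 11945 genes that are not independent replicates. For Dex the correlation was r 0.475 (rho 0.374), with 860 genes higher in both (399 expected by chance), 808 lower in both (321 expected) and 297 in opposite directions (126 higher in experiment 1 and lower in experiment 2, 335 expected, and 171 the other way, 383 expected). For dBRD9 without Dex it was r 0.108 (rho 0.0645), with 88 genes lower in both (12.6 expected), 23 higher in both (7.32 expected) and 25 opposite. All 25 were lower in experiment 1 and higher in experiment 2 (10.8 expected, against 0 the other way, 8.5 expected). For dBRD9 with Dex it was r 0.13 (rho 0.0392), with 76 lower in both (12.4 expected), 8 higher in both (1.97 expected) and 12 opposite, of which 7 were lower in experiment 1 and higher in experiment 2 (2.75 expected) and 5 the other way (8.92 expected).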

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

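Of the tests below, those of transcript length, of the vehicle level, of Ifnb1, of the number of genes called per compound and of the regrouped libraries were chosen after the result was seen; those of GC content, of RNA from another group, of normalization and of the first Dex + LPS library were written down before their values were computed.

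The first Dex + LPS and the first Dex + dBRD9 + LPS library stood apart from the others of their groups. The deviation of the Dex + LPS library followed transcript length (rho -0.683 across genes). Taking out that trend lowered the SD of its deviation from 0.352 to 0.261. The trend was fitted to the same values, so some fall was fixed in advance and is no separate evidence for length. For the Dex + LPS library, RNA of another group is argued against, as the highest squared correlation with another group's difference was 0.0716, and GC content stays open, with rho 0.19 after the length trend was taken out. Neither was tested for the Dex + dBRD9 + LPS library, whose deviation had rho -0.52 with length and an SD of 0.162 before and 0.138 after that trend was taken out. No biological explanation was tested.

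The effect of iBRD9 differed with Dex in 12 of the 16 fixed genes: Brd9 (0.46), Il6 (1.07), Tnf (0.637), Il12b (-0.765), Ifnb1 (3.05), Cxcl10 (1.09), Nos2 (0.535), Ccl2 (-1.12), Fkbp5 (-0.39), Tsc22d3 (-1.25), Dusp1 (-0.671) and Per1 (-0.959), all log2 interactions. It also differed in the lists of type I interferon genes (median 1.77), GTPases (1.89), cell cycle genes (1.21), lysosome genes (-0.32) and neutrophil markers (2.4). For dBRD9 it differed in Il12b (-0.642), and in Cxcl10 (0.462) and Nos2 (0.505), whose calls were lost in several settings (such as DESeq2 size factors, adjusted p = 0.0576 and 0.056, and up to 0.149 and 0.178 when a library was left out).

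Type I interferon genes were lowered less by iBRD9 when Dex was present. A floor at the vehicle level is argued against, because the median member was still 1.65 above vehicle on the log2 scale with Dex + LPS. Of 57 members 48 were called above vehicle, 38 of them over 2-fold, and 3 below. A floor above the vehicle level was not tested. The members summed to 1842 CPM ± 34.3 (SD, n = 3) with vehicle and 19730 ± 416 with LPS. The sum was 6680 ± 653 with iBRD9 + LPS, 7572 ± 281 with Dex + LPS and 7153 ± 320 with Dex + iBRD9 + LPS, so not lower with both than with iBRD9 alone. The lowest median interaction was 1.71 under other normalizations and 1.75 without the first Dex + LPS library or without the length trend, which argues against both as the cause. Ifnb1 had an interaction of 3.05 in the same direction, so a candidate explanation is that Dex had already lowered the interferon transcript that iBRD9 lowers. Whether interferon protein mediates this was not tested. With dBRD9 the interaction of Ifnb1 was -1.05 (adjusted p = 0.47), opposite in sign to the positive median of the interferon list with that compound.

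More genes were called for iBRD9 than for dBRD9 under LPS. Spread or depth alone is argued against, since over the genes called for dBRD9 the slope of iBRD9 on dBRD9 fold changes was 1.71. Its SE of 0.032 is across genes, which are not independent replicates. A single response at 2 strengths for all genes is argued against too, as 10.2% of the genes called for both went opposite ways. These 187 genes are fewer than independent comparisons would give (397 and 257 expected), but the shared controls make the comparisons dependent. Action of iBRD9 beyond BRD9 stays open: 4835 genes were called for iBRD9 only and also differed directly between the compounds, but no group separates compound, dose and mode of action.

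With 3 against 3 libraries only 10 splits exist, so a share under 0.05 cannot be reached: in each of the 8 comparisons of groups in experiment 1, with the other groups kept in the fit, the real split was the 1 with the most calls. The highest other split called 0 genes in 6 of them, 11 genes for Dex + iBRD9 + LPS against Dex + LPS and 1040 for Dex + dBRD9 + LPS against Dex + LPS, where it set the first libraries of both groups on the same side. For the interactions, 100 groupings of the 12 libraries were fitted alone, the real grouping among them, with the genes and TMM factors of all 21 libraries kept (with both taken anew from the 12 libraries, the real groupings had 3585 and 211 genes). For iBRD9 only the real one reached its 3552 genes (highest other 1089), and for dBRD9 4 groupings, the real one among them, reached its 204 genes (highest other 3233, with the LPS libraries kept as a group, so regroupings still carry treatment differences).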

How the results depend on the processing

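No setting reversed a named gene or a list that was called. Over all settings 219 counts of called genes stayed within 1.5 times of the value reported and 37 moved further. In 54 of these 256 counts, over 12 comparisons, the larger side of the split into higher and lower genes changed, as for dBRD9 + LPS against LPS (841 higher and 1262 lower) with library totals alone (1402 and 1039). With library totals alone 795 genes of LPS against vehicle and 183 of IFNγ + LPS against vehicle were called in the other direction, and at most 40 genes in any other setting. Called gene lists fell from 142 to 43 with an estimated correlation. In experiment 1 the interaction of Dex and dBRD9 (429 genes) had 683 with the length trend removed, 947 without both libraries that stood apart, 211 with only the compared groups, and 266 to 890 when a library was left out (lowest without the third LPS library, highest without the first Dex + LPS library; also 269 without the first LPS and 271 without the second Dex + dBRD9 + LPS library). dBRD9 + LPS against LPS (2103) had 3465 without both of those libraries and 3305 with only its groups. With only the compared groups Dex + iBRD9 + LPS against Dex + LPS (4390) had 2283 and Dex + dBRD9 + LPS against Dex + LPS (1999) had 579. The direct comparison of the compounds under Dex (2022) had 1281 to 1632 when a library was left out, lowest without the third Dex + iBRD9 + LPS library. Why these counts moved was not tested.

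In experiment 2, leaving out a library leaves a lone sample that is assumed to vary like the other groups. Dex + IFNγ + LPS against IFNγ + LPS (2655) then had 1530 to 1912, with 1549 and 1530 without the first and second IFNγ + LPS library. dBRD9 + IFNγ + LPS against IFNγ + LPS (243) had 65 to 90 (65 and 67 without the first and second IFNγ + LPS library, 79 and 90 without those with dBRD9), 390 without a filter, 428 with the length trend removed and 410 with only its groups. With Dex (186) the range was 33 to 180 (33 and 37 without the first and second Dex + dBRD9 + IFNγ + LPS library, 65 without the first Dex + IFNγ + LPS library), and the other values were 515, 411 and 511 in the same order. The interaction (1 gene) had 144 without a filter, 38 with the length trend removed, 31 by DESeq2, 38 with only its groups, and 0 to 9 when a library was left out: 0 without any library with dBRD9, 6 without the second IFNγ + LPS library and 9 without the second Dex + IFNγ + LPS library.

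Between groups, the deviations of libraries with the same replicate number correlated at 0.31 for the first Dex + LPS and Dex + dBRD9 + LPS libraries, which stood apart by a length trend, and at -0.263 to 0.13 otherwise. With the replicate number as a block no count moved by over 1.5 times, with 180 and 126 genes for dBRD9 in experiment 2 without and with Dex. The calls of Nos2 without Dex (adjusted p = 0.0786) and of Bicral with Dex (0.0769) were lost there.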

Other observations

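With Dex + LPS against LPS, unfolded protein and integrated stress response genes were higher in 18 of 25 and lower in 5 (19 and 5 adjusted over the list alone, median 0.90, adjusted p = 0.042 with an estimated correlation), such as Dnajb9 (2.02, SE 0.079). The call of mitochondrial transcripts was lost (8 of 12 lower, 11 adjusted over the list alone, median -0.45, adjusted p = 0.3 with an estimated correlation), as were those of macrophage identity (13 of 26 higher, 8 lower, 0.11) and LXR targets (8 of 14 higher, 4 lower, 0.16). With iBRD9 + LPS against LPS, lysosome genes were higher in 18 of 25 and lower in 5 (18 and 5 adjusted over the list alone, median 0.33), a call lost with an estimated correlation (adjusted p = 0.089), with Neu1 at 1.01 (SE 0.057). Mitochondrial transcripts were lower in 10 of 12 with iBRD9 too (11 adjusted over the list alone, median -0.38), without a list call (adjusted p = 0.25, or 0.61 with an estimated correlation). Replication histones, of which 4 were tested and which have no list test, summed to 77.2 CPM ± 2.99 (SD, n = 3) with LPS, 237 ± 13.2 with iBRD9 and 84.6 ± 3.1 with dBRD9, and Hist1h1c rose by 1.88 (SE 0.099) with iBRD9. p53 targets were higher in 9 of 16 and lower in 3 with Dex + dBRD9 + LPS against Dex + LPS (9 and 3 adjusted over the list alone), lost with an estimated correlation (adjusted p = 0.1). Under LPS alone no call was made for immediate early genes with Dex (7 of 21 higher, 11 lower, adjusted p = 0.68 with an estimated correlation), nor in LPS against vehicle for heat shock (8 of 13 higher, 2 lower, 0.56) or oxidative phosphorylation (12 of 25 higher, 2 lower, 0.89).

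Among BAF subunits the lists were not called with an estimated correlation (lowest adjusted p = 0.1, for Dex + dBRD9 + LPS against Dex + LPS), but Bicral rose with dBRD9 in all 4 comparisons: by 0.99 (SE 0.097), 1.33 (SE 0.093), 1.18 (SE 0.25) and 1.01 (SE 0.24), the last 2 in experiment 2, of which the one with Dex was lost in several settings (for example with library totals alone, adjusted p = 0.066, and up to 0.319 when a library was left out). With iBRD9 it rose by 0.49 (SE 0.098) and 0.64 (SE 0.097), less than with dBRD9 in both direct comparisons (-0.50, SE 0.092; -0.69, SE 0.089).

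Markers of other cells were summed to ask whether other cells may contribute RNA. Neutrophil markers, of which Lcn2 is also an acute phase gene of macrophages, fell in all 8 tested members with iBRD9 (8 adjusted over the list alone, median -3.83, adjusted p = 0.0024 with an estimated correlation), and their sum went from 118 CPM ± 6.99 (SD, n = 3) with LPS to 27.2 ± 2.59. In the direct comparison of the compounds they were lower with iBRD9 in 8 of 8 (8 adjusted over the list alone, median -3.12, adjusted p = 0.0015 with an estimated correlation), and under Dex in 6 of 8 (7 adjusted over the list alone, median -0.98, adjusted p = 0.00099 with an estimated correlation). With Dex + LPS the sum was 368 ± 36.1, since Lcn2 rose by 3.19 (SE 0.1). Of the 8 members 4 fell and 2 rose there (median -0.556 but a test in the upward direction, adjusted p = 0.32 with an estimated correlation). The sum was higher with Dex + dBRD9 + LPS (476 ± 19.4) and lower with Dex + iBRD9 + LPS (270.5 ± 1.99). With iBRD9 on top of Dex 6 of 8 fell (7 adjusted over the list alone, median -1.02, adjusted p = 0.0033 with an estimated correlation), and with dBRD9 + IFNγ + LPS against IFNγ + LPS 1 of 10 fell (4 adjusted over the list alone, median -0.74, adjusted p = 0.036 with an estimated correlation). With Dex in experiment 2 dBRD9 had no such call (1 of 10 lower, 1 adjusted over the list alone, median 0.14, 0.66), and with dBRD9 + LPS against LPS it was lost (3 of 8 lower, 3 adjusted over the list alone, median -0.16, 0.059). Stromal markers summed to 1.33 CPM with vehicle, 31.8 with LPS, 44.2 with Dex + LPS, 12.3 with dBRD9 + LPS and 1.43 with iBRD9 + LPS, carried by Pdgfrb (-4.45, SE 0.15), and in experiment 2 to 56.5 to 85.9. B cell markers had at most 51.5 CPM, dendritic cell markers at most 48.2, mast cell and basophil markers at most 2.13 and erythroid markers at most 1.42. T and NK cell markers had 6.40 CPM with vehicle and 109 with IFNγ + LPS in experiment 2, carried by Lck (9.99, SE 0.26), and at most 5.67 in experiment 1.

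A hypothesis was that BRD9 compounds lower the genes that Dex raises, tested with genes chosen in the other experiment. Of 554 genes raised at least 2-fold by Dex in experiment 2, 512 were tested in experiment 1, where Dex moved them by a median of 0.75 on the log2 scale. Under Dex + LPS their median was -0.118 with iBRD9 (SE 0.026, 170 lower, 81 higher, adjusted p = 0.028), which fits the prediction. With dBRD9 it was -0.0486 (SE 0.015, 94 lower, 43 higher, adjusted p = 0.13). By the bound on the median written beforehand, this value fails the prediction. It lies within 2 SE of that bound, a margin that the written prediction did not hold. Without Dex the medians were -0.146 (adjusted p = 0.14) and -0.0475 (adjusted p = 0.31), and the interactions had adjusted p = 0.26 and adjusted p = 0.96, so the effect was not shown to depend on Dex. The 348 genes lowered by Dex in experiment 2 (293 tested) were lower as well, with medians of -1.13 for iBRD9 (adjusted p = 0.0012) and -0.315 for dBRD9 (adjusted p = 0.0018) without Dex, and -0.271 (adjusted p = 0.038) and -0.178 (adjusted p = 0.035) with Dex, so lowering was not particular to the genes that Dex raises. For these lowered genes the iBRD9 effect did differ with Dex (median interaction 0.602, 131 positive, 34 negative, adjusted p = 0.0091). For dBRD9 this was not shown (0.106, adjusted p = 0.46). In the other direction, 622 tested genes raised by Dex in experiment 1 had a median of -0.0411 with dBRD9 under Dex in experiment 2 (adjusted p = 0.31), and 1007 lowered genes had -0.133 (adjusted p = 0.034). Without Dex the medians were -0.001 (adjusted p = 0.37) and 0.0075 (adjusted p = 0.39), so the lowering seen without Dex in experiment 1 was not shown there. The SE of each set median is the SD over 1000 draws of the set's genes with replacement. It treats genes as independent and does not measure the spread between libraries. All these p are from camera (limma) with an estimated correlation, adjusted over all sets and comparisons of this test. The prediction was written for p before this adjustment, which was added later and did not change either outcome.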
